A study of Homo sapiens with 6 samples.

How the data were processed

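RNA sequencing libraries of HCT116 cells, an established human colorectal carcinoma line, were compared between 3 cultures transfected with a control siRNA and 3 transfected with an siRNA against RRN3. Per the labels, the molecule was poly(A) RNA, ribosomal RNA was removed with Ribo-Zero and cDNA was primed with random hexamers. Selection of poly(A) RNA and removal of ribosomal RNA are different ways to prepare a library, and the labels do not say which decided the RNA captured. Values of RNAs that mostly lack a poly(A) tail, such as those of replication-dependent histone genes, SNORD41, SCARNA16 and 7SK, may therefore depend on capture as well as on level. The groups and the replicate numbers 1 to 3 were taken from the labels, and the design text describes 3 biological replicates.

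The deposited table holds 1 TPM value (a length-scaled transcript abundance, relative to all transcripts of the library) per gene symbol and library, as computed by the authors. The submitters' processing notes name STAR, Salmon and GRCh38, without saying what each was used for. Versions, the gene annotation and the filters that the authors applied are not given in the sources used here. The table has 25662 rows, of which 3786 were listed at 0 in all 6 libraries. TPM keeps no sequencing depth, so the depth of each library is unknown and no counting interval was computed. A value of 0 can be a failed estimate, since copies with identical sequence were listed at 0 in some libraries and at high values in others, and is described only as listed at 0.

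Values were analysed as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, and fold changes on this scale understate the change of low genes. Genes with a mean TPM of at least 1 over the 6 libraries were tested, which kept 12157. The model held the group alone, variances were moderated with eBayes with an intensity trend, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. In the text, a gene rose, fell or changed only if it passed this threshold, and levels are mean TPM ± SD with n = 3 in each group. RRN3 was also tested with an exact two-sided permutation test, whose smallest possible p with 3 against 3 is 0.1.

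There were 35 gene lists, written from textbook knowledge before the data were examined. The 32 lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, using the intensity trend, with Benjamini-Hochberg adjustment over the lists. The 3 lists of immune cell, fibroblast and endothelial markers had fewer measured members. Camera with an estimated correlation and fry were run as alternatives, with statmod 1.5.0 installed. For each list the members past the threshold were counted over all genes tested and again adjusted over the list alone.

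The genes named were fixed by a rule before the data were examined. RRN3 and its copies came first. They were followed by the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold with a mean TPM of at least 5 in the higher group and no overlap between the groups. For each list past the camera threshold up to 4 members in its direction with the smallest adjusted p were named. For each other list up to 2 members of either direction were named, and up to 4 for polymerase I transcription. Not every gene that this rule selects is given here. Genes named outside this rule are said to have been chosen after their values were seen.

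Coordinates, transcript GC content and length came from GENCODE release 29 on GRCh38, matched by symbol, which gave a GC value for 12100 of the 12157 tested genes (99.5%). GC trends were removed per library by loess with a span of 0.3. Annotation was read with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

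The alternatives fixed before the data were examined were other pseudocounts, other filters on low values, median-of-ratios and quantile scaling, TPM rescaled without mitochondrial and cytosolic ribosomal protein genes, eBayes without a trend and with robust moderation, a replicate block, a minimum log2 change of 1, and leaving out each library in turn. The GC correction and the fit without both libraries numbered 1 were added after the data had been seen.

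The fit and camera were tested on simulated data made from the means and spreads of the 12157 genes, with 200 changed genes in each of 20 runs of the comparison of RRN3 siRNA with control siRNA. Of genes given a log2 change of 0.5, 15.2% were recovered, of those given 1, 62.3%, and of those given 2, 93.3%. On average 4.56% of the calls were false. A list shifted by a log2 change of 0.5 was called in all 20 runs. Only 200 genes changed per run, against 3679 called in the data, so the adjusted threshold was stricter in the simulation. These shares therefore do not describe recovery in the real comparison. Simulated genes varied independently of one another, so deviations shared by many genes of a library were absent. The runs say nothing of how camera behaves where genes of a list vary together.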

Results

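Gene expression was measured by RNA sequencing in HCT116 cells, a human colorectal carcinoma line, after transfection with a control siRNA (n = 3) or an siRNA against RRN3 (n = 3). RRN3, also called TIF-IA, is the factor that brings RNA polymerase I to the promoters of the ribosomal RNA genes. The comparison asks which transcripts change when this factor is depleted. The 6 libraries had summed TPM values of 991305 to 992042, between 17361 and 18632 genes above 0, and an unknown sequencing depth. Spearman correlations across genes were 0.976 to 0.989 within groups and 0.938 to 0.952 between groups. The first principal component, with 59.9% of the variance, separated the groups. The second, with 23.4%, set both libraries numbered 1 (17.8 for control siRNA and 31.6 for RRN3 siRNA) apart from the other libraries, all of which were below 0. These 2 libraries held more of the GC-poor transcripts than the others of their group, with correlations across genes between GC content and deviation from the group mean of -0.46 and -0.51. Genes are not independent replicates, so these correlations describe the libraries only.

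**Figure D1:**
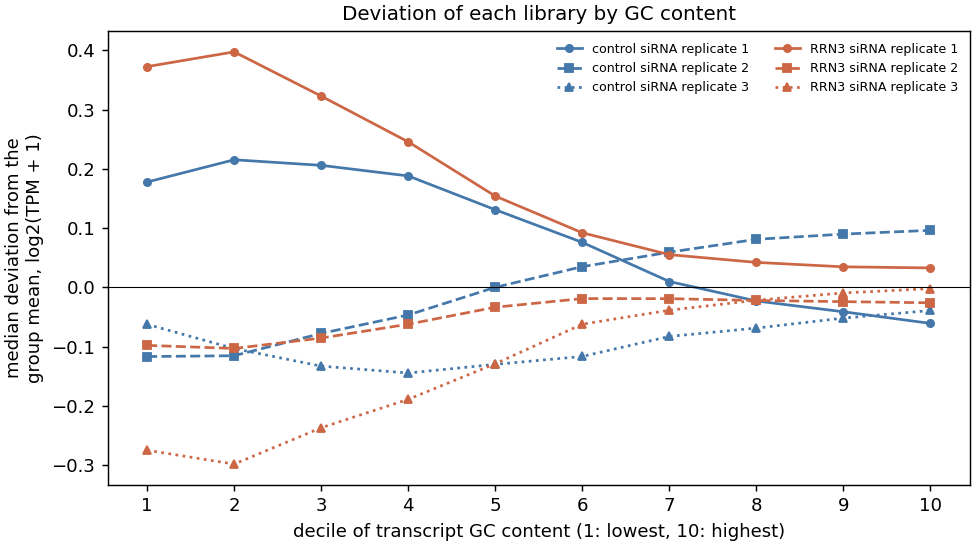
Median deviation of each library from its group mean, in log2(TPM + 1), plotted for 10 bins of transcript GC content, with 1 line per library and a color per group. In the lowest bin replicate 1 lay 0.18 above the mean of the control siRNA group and 0.37 above that of the RRN3 siRNA group, while RRN3 siRNA replicate 3 lay at -0.27.

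RRN3 fell to 9.73% of its control level, from 16.6 ± 3.79 to 1.61 ± 0.953 TPM (SD, n = 3 per group). The control siRNA libraries held 20.9, 14.7 and 14.1 TPM and the RRN3 siRNA libraries 2.70, 1.22 and 0.925 TPM, so the groups did not overlap. The log2 change was -2.79 (SE 0.27) with a limma adjusted p of 0.000301. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. RRN3 (ENSG00000085721) lies on the minus strand of chromosome 16 at 15060022 to 15094317 in GRCh38. Its pseudogenes on the same chromosome share sequence with it, so reads can be split between them. RRN3P3, at 22418672 to 22437715, had 0.616 ± 0.0418 TPM in control siRNA and 1.09 ± 0.242 TPM in RRN3 siRNA libraries, which is below the minimum for testing. RRN3P2 was listed at 0 in every library, and RRN3P1 was not analysed here.

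**Figure D2:**
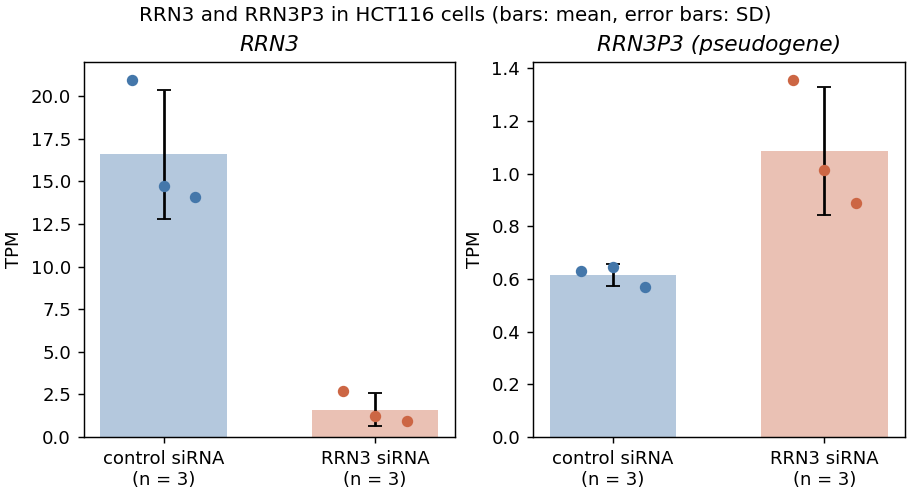
TPM of RRN3 and of its pseudogene RRN3P3 in each library, with points for the 3 libraries of a group, bars for their mean and error bars for the SD. RRN3 lay at 14.1 TPM or more in the control siRNA libraries and at 2.70 TPM or less in the RRN3 siRNA libraries.

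In cells given RRN3 siRNA 52 of 70 measured p53 target genes rose, while 55 of 60 G1/S and 52 of 53 G2/M genes fell, with the tests of these lists given with each list. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 6.64-fold, from 319 ± 25.6 to 2119.7 ± 62.3 TPM. MCM5, a subunit of the replicative helicase, fell 5.28-fold, from 112 ± 10.3 to 21.3 ± 1.37 TPM. CDC20, an activator of the anaphase-promoting complex, fell 4.6-fold, from 310.2 ± 27.6 to 67.4 ± 2.89 TPM. Of 12157 genes tested, 3679 changed, of which 1367 rose and 2312 fell. Counts of list members that rose or fell are to be read against these totals, in which falls outnumbered rises. The larger number of falls depended on scaling, since 2017 genes rose and 2115 fell after median-of-ratios scaling, 2205 and 2284 after quantile normalization, and 2758 and 2674 once the GC trend of each library was removed. With TPM rescaled without mitochondrial and ribosomal protein genes, falls still outnumbered rises, with 1745 genes rising and 2360 falling. The median log2 change was 0.01 in the tenth of genes with the lowest GC content and -0.18 in that with the highest. Without RRN3 siRNA replicate 2 the number of changed genes was 2240 (788 rose and 1452 fell), and without control siRNA replicate 3 the number that rose was 893. With a replicate block 5546 genes changed (2295 rose and 3251 fell).

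Among the largest rises, NRG1, a ligand of ERBB receptors, rose from 0.919 ± 0.247 to 14 ± 0.0889 TPM (log2 change 2.98, SE 0.15, limma adjusted p = 2.46e-05). TP53I3, a p53-induced oxidoreductase, rose from 10.1 ± 1.72 to 78.4 ± 2.24 TPM, and ACTA2, smooth muscle actin, from 4.43 ± 0.453 to 32.1 ± 1.99 TPM. ZBED2 rose from 3.07 ± 0.591 to 23.1 ± 1.61 TPM, and KLK5, a secreted serine protease, from 1.59 ± 0.299 to 13.6 ± 0.555 TPM. The histone gene H2BC5 and CDKN1A were also among the largest rises. A further 4 were listed at 0 in control siRNA replicates 2 and 3, and included the small RNAs SNORD41, SCARNA16 and the mitochondrial tRNA gene MT-TT. SNORD41 was at 5.43 TPM in control siRNA replicate 1 and at 6.78, 14.9 and 42.9 TPM in the RRN3 siRNA libraries. TMEM265 was at 0.837 TPM in control siRNA replicate 1 and at 6.64, 9.54 and 11.8 TPM after RRN3 siRNA. Leaving out control siRNA replicate 2, control siRNA replicate 3 or RRN3 siRNA replicate 2 ended the calls of SNORD41 (adjusted p = 0.108, 0.0833 and 0.0559) and of MT-TT (adjusted p = 0.104, 0.0802 and 0.0713). Both also ended without a filter on low values (adjusted p = 0.0658 and 0.0642).

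Among the largest falls, SLC25A10, the mitochondrial dicarboxylate carrier, fell from 87.6 ± 11.2 to 13 ± 1.16 TPM (log2 change -2.66, SE 0.12, limma adjusted p = 1.53e-05). FGFRL1, a receptor related to the fibroblast growth factor receptors, fell from 54 ± 6.88 to 8.93 ± 0.746 TPM. RAB26, a small GTPase, fell from 13.2 ± 0.37 to 1.39 ± 0.218 TPM, and ZDHHC12, a palmitoyltransferase, from 56.3 ± 4.84 to 10.2 ± 0.527 TPM. CDT1, which licenses replication origins, fell from 84.8 ± 10.2 to 17.5 ± 1.46 TPM, and TROAP from 69.1 ± 1.38 to 11.9 ± 0.313 TPM. RDM1 fell from 11 ± 2.72 to 1.29 ± 0.302 TPM, and CD68, a lysosomal membrane protein, from 8.29 ± 0.88 to 0.737 ± 0.154 TPM. TREX1, a DNA exonuclease, and the minor spliceosomal RNA gene RNU6ATAC completed the 12, each listed at 0 in at least 1 RRN3 siRNA library. The RNU6ATAC call ended without a filter on low values (adjusted p = 0.0883) and when any of control siRNA replicates 1, 2 and 3 or RRN3 siRNA replicate 3 was left out (adjusted p = 0.0931, 0.114, 0.0506 and 0.0687).

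Of the p53 target genes, 52 of 70 measured rose, 3 fell and 15 did not pass the test. In the p53 list, the median log2 change was 0.76. Camera gave adjusted p = 3.05e-21, or adjusted p = 0.703 with the estimated correlation of 0.290. BTG2, an antiproliferative protein, rose from 48.9 ± 5.16 to 196 ± 0.686 TPM, and EPHA2, a receptor tyrosine kinase, from 103 ± 9.66 to 292 ± 4.71 TPM. The 3 that fell, named after their values were seen, were KITLG, the ligand of the KIT receptor, the keratin gene KRT15, and TP53I11, with log2 changes of -1.33, -0.62 and -0.51. Among the members that did not pass, also named after their values were seen, DDB2, a DNA damage recognition factor, had log2 change 0.16 with adjusted p = 0.204. In the p53 list 55 rose and 5 fell when adjusted over the list alone.

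Among genes of the G1/S transition, MCM7 fell from 306 ± 16 to 99.2 ± 3.45 TPM and TK1, thymidine kinase, from 314 ± 22.5 to 103 ± 4.2 TPM. Of these genes, 1 of 60 measured rose, 55 fell and 4 did not pass the test. In the G1/S list, the median log2 change was -1.46. Camera gave adjusted p = 4.30e-23, or adjusted p = 0.703 with the estimated correlation of 0.539. The member that rose was CCNE1, cyclin E1, from 31.1 ± 2.05 to 54.1 ± 4.25 TPM (limma adjusted p = 0.000896), named after its values were seen. In the G1/S list 1 rose and 59 fell when adjusted over the list alone. Of the G2/M genes, 0 of 53 measured rose, 52 fell and 1 did not pass the test. In the G2/M list, the median log2 change was -1.59. Camera gave adjusted p = 7.55e-24, or adjusted p = 0.703 with the estimated correlation of 0.559. AURKB, the kinase of the chromosomal passenger complex, fell from 118 ± 5.07 to 28.8 ± 2.3 TPM, and its partner BIRC5 from 171 ± 2.51 to 49 ± 4.11 TPM. UBE2C, a ubiquitin-conjugating enzyme of mitosis, fell from 195 ± 1.5 to 64.1 ± 1.34 TPM. The member that did not pass was BUB3, at 156 TPM in control siRNA and 155 TPM in RRN3 siRNA libraries, named after its values were seen. In the G2/M list 0 rose and 52 fell when adjusted over the list alone. Of the DNA repair genes, 0 of 27 measured rose, 18 fell and 9 did not pass the test. None of those that fell is in the G1/S or G2/M list, which follows from how the lists were written. It does not show that their fall was separate from that of the cell cycle genes. In the DNA repair list, the median log2 change was -0.90 and camera gave adjusted p = 1.25e-05, or adjusted p = 0.784 with an estimated correlation. The DNA repair genes that fell included the Fanconi anemia genes FANCG, from 38.4 ± 1.55 to 9.28 ± 0.395 TPM, and FANCA, from 51.8 ± 1.23 to 18.4 ± 2.01 TPM. The recombination genes XRCC3 and RAD54L fell from 37.2 ± 1.75 to 10.1 ± 0.165 TPM and from 18.6 ± 3.89 to 3.89 ± 0.397 TPM. In the DNA repair list 1 rose and 18 fell when adjusted over the list alone.

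**Figure D3:**
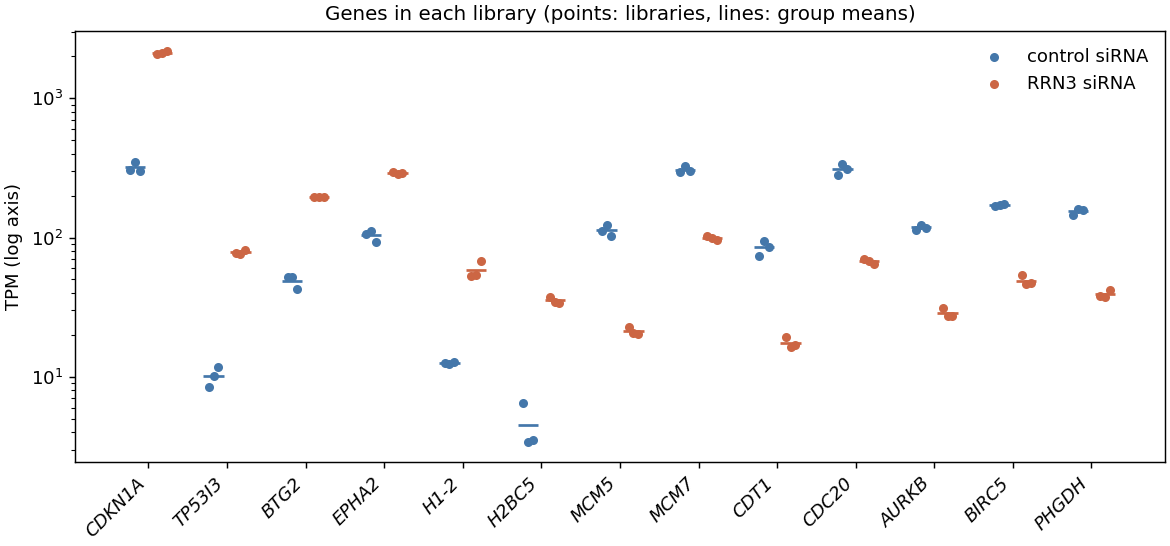
TPM on a log axis of 13 named genes in each library, with points for the 3 libraries of a group and lines for group means. CDKN1A, TP53I3, BTG2, EPHA2, H1-2 and H2BC5 lay higher in every RRN3 siRNA library than in any control siRNA library, and MCM5, MCM7, CDT1, CDC20, AURKB, BIRC5 and PHGDH lower.

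Lists tied to ribosome production had medians nearer to 0 than the cell cycle lists. Of the polymerase I transcription genes, 0 of 16 measured rose, 3 fell and 13 did not pass the test. In the polymerase I transcription list, the median log2 change was -0.07 and camera gave adjusted p = 0.777, or adjusted p = 0.917 with an estimated correlation. The subunit genes POLR1H and POLR1D fell from 37.6 ± 1.38 to 29.1 ± 1.14 TPM and from 165 ± 8.19 to 138 ± 6.41 TPM. UBTF, the upstream binding factor of ribosomal RNA genes, fell from 48 ± 4.01 to 38.2 ± 3.09 TPM. POLR1A, the largest subunit of the enzyme, was at 22.5 TPM in control siRNA and 28.6 TPM in RRN3 siRNA libraries, with adjusted p = 0.0866. Median-of-ratios scaling ended the calls of POLR1H, POLR1D and UBTF (adjusted p = 0.13, 0.353 and 0.114), as did leaving out RRN3 siRNA replicate 2 (adjusted p = 0.0752, 0.117 and 0.122). The POLR1H and POLR1D calls ended with quantile normalization (adjusted p = 0.0586 and 0.0757), and the POLR1D and UBTF calls ended without a variance trend (adjusted p = 0.0980 and 0.0772), without control siRNA replicate 1 (adjusted p = 0.0799 and 0.0991) and without RRN3 siRNA replicate 3 (adjusted p = 0.0645 and 0.147). The POLR1D call also ended after rescaling (adjusted p = 0.106), removal of the GC trend (adjusted p = 0.289), without control siRNA replicate 3 (adjusted p = 0.104), RRN3 siRNA replicate 1 (adjusted p = 0.0987) or both libraries numbered 1 (adjusted p = 0.124), and the UBTF call without a filter (adjusted p = 0.0711) or control siRNA replicate 2 (adjusted p = 0.131). POLR1A passed upward with a replicate block, without RRN3 siRNA replicate 1, with the GC trend removed and without both libraries numbered 1 (adjusted p = 0.0361, 0.0453, 0.0318 and 0.0124). In the polymerase I transcription list 0 rose and 0 fell when adjusted over the list alone, and 4 had an unadjusted p under 0.05. The direction of the polymerase I list turned upward without both libraries numbered 1 (adjusted p = 0.967). Of the ribosome biogenesis factors, 20 of 128 measured rose, 12 fell and 96 did not pass the test. In the ribosome biogenesis list, the median log2 change was 0.12 and camera gave adjusted p = 0.0155, or adjusted p = 0.889 with an estimated correlation. RRS1 and RRP12, both assembly factors, rose from 24.9 ± 1.01 to 52.7 ± 2.79 TPM and from 33.6 ± 0.683 to 55.7 ± 1.58 TPM. EIF6 rose from 251 ± 18.2 to 369 ± 37.4 TPM and the helicase gene DDX49 from 35.8 ± 3.91 to 53.4 ± 3.01 TPM. In the ribosome biogenesis list 20 rose and 12 fell when adjusted over the list alone. The ribosome biogenesis call ended in fry (adjusted p = 0.505). Of the polymerase III transcription genes, 2 of 26 measured rose, 3 fell and 21 did not pass the test. POLR3K fell from 28 ± 1.97 to 15.8 ± 2.14 TPM and GTF3C5 from 78 ± 3.29 to 58.8 ± 1.35 TPM. In the polymerase III transcription list, the median log2 change was 0.05 and camera gave adjusted p = 0.472, or adjusted p = 0.917 with an estimated correlation. In the polymerase III transcription list 2 rose and 3 fell when adjusted over the list alone. The GTF3C5 call ended with median-of-ratios scaling (adjusted p = 0.0674).

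Of the cytosolic ribosomal protein genes, 2 of 79 measured rose, 21 fell and 56 did not pass the test. In the cytosolic ribosomal protein list, the median log2 change was -0.08 and camera gave adjusted p = 0.137, or adjusted p = 0.917 with an estimated correlation. RPS28 fell from 995 ± 96.8 to 429 ± 20.04 TPM and RPL3 from 3147 ± 29.6 to 1745 ± 5.68 TPM. In the cytosolic ribosomal protein list 2 rose and 21 fell when adjusted over the list alone. Without control siRNA replicate 2 or RRN3 siRNA replicate 3 this list passed downward (adjusted p = 0.00685 and 0.00498), and without RRN3 siRNA replicate 1 its direction was up (adjusted p = 0.802), as it was without both libraries numbered 1 (adjusted p = 0.940). Of the mitochondrial ribosomal protein genes, 5 of 77 measured rose, 18 fell and 54 did not pass the test. MRPL11 fell from 150.0 ± 8.4 to 76.7 ± 2.64 TPM and MRPS23 rose from 121 ± 6.81 to 205 ± 2.91 TPM. In the mitochondrial ribosomal protein list, the median log2 change was -0.02 and camera gave adjusted p = 0.753, or adjusted p = 0.917 with an estimated correlation. In the mitochondrial ribosomal protein list 5 rose and 18 fell when adjusted over the list alone. Its direction turned upward after median-of-ratios scaling, after rescaling without mitochondrial and ribosomal protein genes and after removal of the GC trend (adjusted p = 0.592, 0.905 and 0.888), and without control siRNA replicate 3, RRN3 siRNA replicate 1 or both libraries numbered 1 (adjusted p = 0.820, 0.538 and 0.650). Of the small nucleolar RNA host genes, 1 of 28 measured rose, 6 fell and 21 did not pass the test. SNHG19 fell from 71.7 ± 5.92 to 35.7 ± 4.42 TPM and SNHG7 from 60.3 ± 5.02 to 37.4 ± 3.13 TPM. In the host gene list, the median log2 change was -0.18 and camera gave adjusted p = 0.198, or adjusted p = 0.917 with an estimated correlation. In the host gene list 1 rose and 5 fell when adjusted over the list alone. Without control siRNA replicate 2 it passed (adjusted p = 0.0126).

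Of the replication-dependent histone genes, whose products package newly replicated DNA, 10 of 13 measured rose, 1 fell and 2 did not pass the test. In the histone list, the median log2 change was 0.85 and camera gave adjusted p = 6.55e-06, or adjusted p = 0.308 with an estimated correlation. The linker histone gene H1-2 rose from 12.6 ± 0.204 to 58.1 ± 8.23 TPM, H2BC12 from 16.7 ± 1.26 to 57.9 ± 3.45 TPM and H2BC5 from 4.48 ± 1.77 to 35.3 ± 2.05 TPM. H2AC18 rose from 4.66 ± 0.799 to 15.8 ± 0.0396 TPM, while the gene that fell, H4C12, named after its values were seen, had log2 change -0.65 and adjusted p = 0.013. Reads can be split between histone genes of near-identical sequence, and only 13 of the 49 listed histone genes in the table reached the minimum TPM. In the histone list 10 rose and 1 fell when adjusted over the list alone. Without a filter on low values the list did not pass (adjusted p = 0.118).

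Of the MYC target genes, 5 of 59 measured rose, 19 fell and 35 did not pass the test. In the MYC list, the median log2 change was -0.26 and camera gave adjusted p = 0.00572, or adjusted p = 0.889 with an estimated correlation. ODC1, the first enzyme of polyamine synthesis, fell from 248 ± 19.3 to 66.3 ± 7.66 TPM and RANBP1 from 239 ± 10.7 to 151 ± 6.29 TPM. The amino acid transporter subunit gene SLC3A2 fell from 274 ± 3.69 to 193 ± 6.3 TPM and POLR2H from 239.9 ± 11 to 163 ± 5.68 TPM. In the MYC list 5 rose and 21 fell when adjusted over the list alone. The call of the list ended in fry (adjusted p = 0.0542). MYC itself, named after its values were seen, rose from 192 ± 26 to 258 ± 24 TPM (adjusted p = 0.0261). POLR2A, the largest subunit of RNA polymerase II, also named after its values were seen, fell from 121 ± 16.6 to 32.9 ± 3.1 TPM (limma adjusted p = 5.37e-05). Of the ATF4 target genes of the integrated stress response, 4 of 42 measured rose, 20 fell and 18 did not pass the test. In the ATF4 list, the median log2 change was -0.47 and camera gave adjusted p = 0.0178, or adjusted p = 0.889 with an estimated correlation. PHGDH, the first enzyme of serine synthesis, fell from 154 ± 8.05 to 39.2 ± 2.47 TPM and the alanyl-tRNA synthetase gene AARS1 from 128 ± 12.2 to 53.2 ± 1.85 TPM. PCK2 fell from 21.2 ± 1.13 to 8.1 ± 0.19 TPM and CHAC1 from 13.8 ± 3.55 to 3.95 ± 0.397 TPM. The 4 that rose, named after their values were seen, were ATF3, GDF15, SARS1 and SESN2. In the ATF4 list 4 rose and 21 fell when adjusted over the list alone. Of the spliceosome genes, 1 of 44 measured rose, 12 fell and 31 did not pass the test. SNRPA fell from 130.2 ± 13.7 to 66.2 ± 2.57 TPM and SNRPB from 608 ± 34.6 to 354 ± 26.9 TPM. SNRNP70 fell from 249 ± 22.3 to 162 ± 8.34 TPM and SNRPF from 442 ± 28.6 to 301 ± 22.8 TPM. In the spliceosome list, the median log2 change was -0.23 and camera gave adjusted p = 0.0237, or adjusted p = 0.889 with an estimated correlation. In the spliceosome list 1 rose and 12 fell when adjusted over the list alone. The spliceosome call ended with median-of-ratios scaling (adjusted p = 0.0683), without a variance trend (adjusted p = 0.0507), without control siRNA replicate 1 (adjusted p = 0.0550) and in fry (adjusted p = 0.144).

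Of the epithelial-mesenchymal transition genes, 9 of 20 measured rose, 2 fell and 9 did not pass the test. In the epithelial-mesenchymal list, the median log2 change was 0.44 and camera gave adjusted p = 0.000881, or adjusted p = 0.784 with an estimated correlation. Beside ACTA2, the receptor tyrosine kinase gene AXL rose from 7.93 ± 0.97 to 46 ± 3.43 TPM and the myosin light chain gene MYL9 from 38.9 ± 1.45 to 85.1 ± 4.23 TPM. The 2 that fell, named after their values were seen, were S100A4 and SNAI1, the latter a transcription factor of this transition, with log2 changes of -0.49 and -0.55. In the epithelial-mesenchymal list 9 rose and 3 fell when adjusted over the list alone. None of the 9 that rose was in the p53 list. Of the epithelial junction and keratin genes, 8 of 28 measured rose, 3 fell and 17 did not pass the test. In the junction and keratin list, the median log2 change was 0.07 and camera gave adjusted p = 0.0312, or adjusted p = 0.889 with an estimated correlation. The keratin genes KRT7 and KRT80 rose from 9.24 ± 0.572 to 40.5 ± 0.149 TPM and from 4.97 ± 0.481 to 20.8 ± 1.64 TPM. KRT18 rose from 1389 ± 98.1 to 3174 ± 241 TPM and KRT8 from 2798 ± 321 to 6409 ± 235 TPM. In the junction and keratin list 8 rose and 3 fell when adjusted over the list alone. The call of this list ended with quantile normalization (adjusted p = 0.0536), with median-of-ratios scaling (adjusted p = 0.0683), without a filter (adjusted p = 0.0817), without a variance trend (adjusted p = 0.0507), without control siRNA replicate 1 (adjusted p = 0.0554), without RRN3 siRNA replicate 1 (adjusted p = 0.0531) and without both (adjusted p = 0.0594). Of the immediate early genes, 12 of 36 measured rose, 8 fell and 16 did not pass the test. In the immediate early list, the median log2 change was 0.27 and camera gave adjusted p = 0.0403, or adjusted p = 0.917 with an estimated correlation. In the immediate early list 15 rose and 9 fell when adjusted over the list alone. CCN1 rose from 16.5 ± 1.62 to 41.8 ± 5.21 TPM. The transcription factor genes JUN and FOSL1 rose from 14 ± 1.5 to 35 ± 4.54 TPM and from 151 ± 12.4 to 249 ± 9.04 TPM. BTG2 is also a member. The immediate early call ended without control siRNA replicate 1, control siRNA replicate 3 or both libraries numbered 1 (adjusted p = 0.0719, 0.0670 and 0.0594) and with median-of-ratios or quantile scaling (adjusted p = 0.0583 and 0.0728). It also ended with a mean TPM of at least 5 (adjusted p = 0.0547), without a variance trend (adjusted p = 0.0507) and in fry (adjusted p = 0.274).

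Of the apoptosis regulators, 10 of 36 measured rose, 4 fell and 22 did not pass the test, and 7 of those that rose were also in the p53 list. In the apoptosis list, the median log2 change was 0.06 and camera gave adjusted p = 0.0355, or adjusted p = 0.889 with an estimated correlation. BAX and BAK1, which permeabilize the outer mitochondrial membrane, rose from 139 ± 1.91 to 252 ± 14.5 TPM and from 33.5 ± 2.28 to 64.4 ± 3.71 TPM. The death receptor gene TNFRSF10B rose from 96.1 ± 13.4 to 232 ± 19.7 TPM and the antiapoptotic BCL2L1 from 182 ± 11.3 to 280.3 ± 7.15 TPM. In the apoptosis list 12 rose and 5 fell when adjusted over the list alone. The apoptosis call ended with median-of-ratios scaling (adjusted p = 0.0583), with quantile normalization (adjusted p = 0.0636), without a variance trend (adjusted p = 0.0507), without control siRNA replicate 1 (adjusted p = 0.0572) and in fry (adjusted p = 0.237). Of the autophagy and lysosome genes, 11 of 52 measured rose, 2 fell and 39 did not pass the test. In the autophagy and lysosome list, the median log2 change was 0.15 and camera gave adjusted p = 0.0123, or adjusted p = 0.889 with an estimated correlation. The lysosomal genes GAA and PSAP rose from 60.4 ± 3.79 to 102 ± 3.07 TPM and from 591 ± 50.2 to 934 ± 13 TPM. The autophagy genes GABARAPL2 and ATG7 rose from 113 ± 3.92 to 157 ± 3.59 TPM and from 17.8 ± 1.54 to 27 ± 2.34 TPM. In the autophagy and lysosome list 11 rose and 2 fell when adjusted over the list alone. The autophagy and lysosome call ended in fry (adjusted p = 0.261).

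Transcripts of the mitochondrial genome made up 24.9 ± 1.37% of TPM in control siRNA and 28.3 ± 1.35% in RRN3 siRNA libraries (SD, n = 3), and cytosolic ribosomal protein transcripts 19.2 ± 1.26% and 17 ± 1.14%. Of the mitochondrial genome transcripts, 5 of 13 measured rose, 0 fell and 8 did not pass the test. In the mitochondrial genome list, the median log2 change was 0.24 and camera gave adjusted p = 0.00488, or adjusted p = 0.889 with an estimated correlation. In the mitochondrial genome list 5 rose and 0 fell when adjusted over the list alone. MT-ND1 rose from 3777 ± 302 to 6201 ± 361 TPM and MT-ND5 from 4286 ± 232 to 5296 ± 64.9 TPM. MT-CYB rose from 6616 ± 374 to 8303 ± 469 TPM and MT-ND6 from 8362 ± 433 to 10114 ± 215 TPM. The list call ended with median-of-ratios scaling, quantile normalization and removal of the GC trend (adjusted p = 0.153, 0.484 and 0.348), and MT-CYB turned to a log2 change of -0.050 with quantile normalization. Quantile normalization gives genes of equal rank the same value in every library. It can therefore remove a change of transcripts as abundant as these by construction. The calls of MT-ND5, MT-CYB and MT-ND6 ended with median-of-ratios scaling (adjusted p = 0.128, 0.171 and 0.214), removal of the GC trend (adjusted p = 0.216, 0.280 and 0.331), without a filter (adjusted p = 0.0622, 0.0895 and 0.138), without a variance trend (adjusted p = 0.0512, 0.0523 and 0.0715), and without control siRNA replicate 3 (adjusted p = 0.0707, 0.0540 and 0.126) or RRN3 siRNA replicate 2 (adjusted p = 0.0927, 0.109 and 0.168). Those of MT-CYB and MT-ND6 also ended with quantile normalization (adjusted p = 0.442 and 1), after rescaling (adjusted p = 0.0624 and 0.0746), and without control siRNA replicate 1 (adjusted p = 0.0570 and 0.0726) or RRN3 siRNA replicate 3 (adjusted p = 0.0781 and 0.0774). Of the nuclear-encoded genes of oxidative phosphorylation, 4 of 76 measured rose, 22 fell and 50 did not pass the test. In the oxidative phosphorylation list, the median log2 change was -0.14 and camera gave adjusted p = 0.0403, or adjusted p = 0.889 with an estimated correlation. CYC1, cytochrome c1, fell from 499 ± 32.6 to 313 ± 20.5 TPM and ATP5MC3 from 672 ± 29.4 to 492 ± 24 TPM. The complex I genes NDUFS3 and NDUFB10 fell from 150.1 ± 6.81 to 91.5 ± 7.9 TPM and from 257 ± 15.5 to 179 ± 5.07 TPM. In the oxidative phosphorylation list 5 rose and 24 fell when adjusted over the list alone. The oxidative phosphorylation call ended with median-of-ratios and quantile scaling (adjusted p = 0.402 and 0.118), after rescaling (adjusted p = 0.171), with the GC trend removed (adjusted p = 0.202), with a mean TPM of at least 5 (adjusted p = 0.0520), without a variance trend (adjusted p = 0.118) and in fry (adjusted p = 0.102). It also ended without control siRNA replicate 3, RRN3 siRNA replicate 1 or both libraries numbered 1 (adjusted p = 0.362, 0.765 and 0.636), and the ATP5MC3 call ended with median-of-ratios scaling and removal of the GC trend (adjusted p = 0.0859 and 0.0740).

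**Figure D4:**
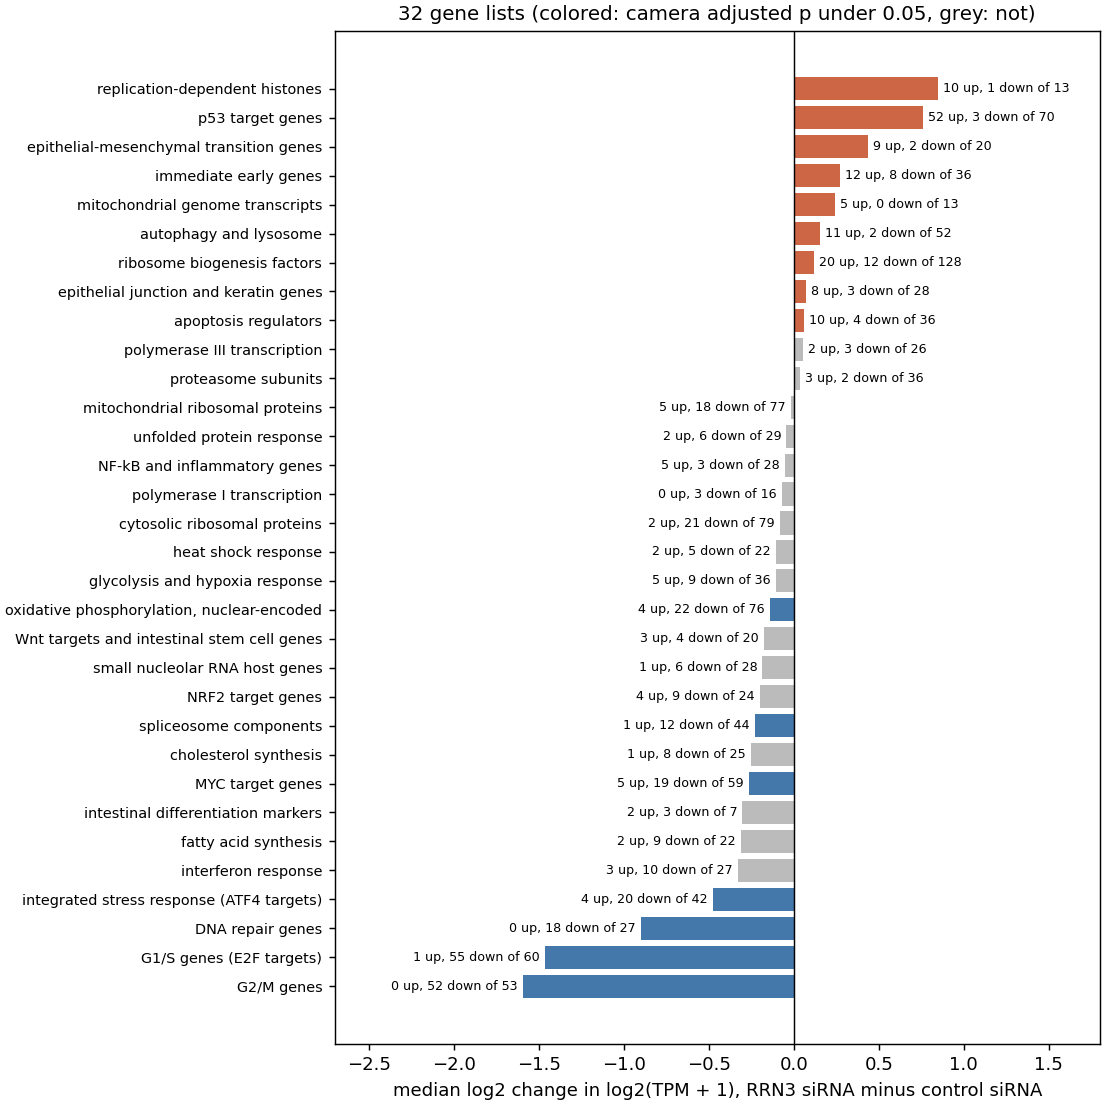
Median log2 change, RRN3 siRNA minus control siRNA, of the 32 tested lists, with the numbers of members that rose and fell of those measured, and color for lists past the camera threshold. G2/M genes have the lowest median, -1.59, and replication-dependent histone genes the highest, 0.85.

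With a preset correlation 16 of the 32 lists passed, 9 upward and 7 downward. None of the 32 passed camera with an estimated correlation, where the lowest adjusted p was 0.308 and 1 list had an unadjusted p under 0.05. The estimated correlations ran from 0.018 (interferon response) to 0.636 (immediate early) and were above the preset 0.01 in every list. Where genes of a list vary together more than the preset allows, the camera p-values at the preset are too small. In fry 12 passed, a test of whether the genes of a list move one way, which compares them with no other genes. Among the lists that did not pass, the interferon response list had 3 of 27 genes that rose and 10 that fell. OASL fell from 9.21 ± 0.414 to 3.03 ± 0.34 TPM and PSMB9 from 13 ± 1.84 to 4.2 ± 0.443 TPM. In the interferon response list, the median log2 change was -0.33 and camera gave adjusted p = 0.127, or adjusted p = 0.784 with an estimated correlation. In the interferon response list 3 rose and 11 fell when adjusted over the list alone. Without a filter on low values it passed downward (adjusted p = 0.0144), as it did in fry (adjusted p = 0.00690). Of the cholesterol synthesis genes, 1 of 25 measured rose, 8 fell and 16 did not pass the test. The enzyme genes EBP and ACAT2 fell from 148 ± 4.65 to 51.3 ± 2.58 TPM and from 66.2 ± 4.46 to 35.1 ± 2.81 TPM. In the cholesterol synthesis list, the median log2 change was -0.25 and camera gave adjusted p = 0.0572, or adjusted p = 0.889 with an estimated correlation. In the cholesterol synthesis list 1 rose and 9 fell when adjusted over the list alone. That list passed in fry (adjusted p = 0.0457), without a filter (adjusted p = 0.0131) and without control siRNA replicate 3 (adjusted p = 0.0491). Of the fatty acid synthesis genes, 2 of 22 measured rose, 9 fell and 11 did not pass the test. FADS3 rose from 35.4 ± 2.47 to 67.1 ± 5.46 TPM and the transcription factor gene SREBF1 fell from 129 ± 9.89 to 68.9 ± 12.6 TPM. In the fatty acid synthesis list, the median log2 change was -0.31 and camera gave adjusted p = 0.273, or adjusted p = 0.917 with an estimated correlation. In the fatty acid synthesis list 2 rose and 10 fell when adjusted over the list alone. Of the NRF2 target genes, 4 of 24 measured rose, 9 fell and 11 did not pass the test. The quinone reductase gene NQO1 fell from 634 ± 8.01 to 247 ± 5.36 TPM and the ferritin gene FTL from 3267 ± 203 to 1689 ± 52.1 TPM. In the NRF2 list, the median log2 change was -0.20 and camera gave adjusted p = 0.273, or adjusted p = 0.917 with an estimated correlation. In the NRF2 list 4 rose and 9 fell when adjusted over the list alone. In fry this list passed (adjusted p = 0.0457).

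Of the glycolysis and hypoxia response genes, 5 of 36 measured rose, 9 fell and 22 did not pass the test. The glucose transporter genes SLC2A1 and SLC2A3 rose from 285 ± 33.6 to 940.1 ± 35.7 TPM and from 0.478 ± 0.0682 to 5.99 ± 1.15 TPM. In the glycolysis and hypoxia response list, the median log2 change was -0.10 and camera gave adjusted p = 0.753, or adjusted p = 0.917 with an estimated correlation. In the glycolysis and hypoxia response list 5 rose and 11 fell when adjusted over the list alone. Of the unfolded protein response genes, 2 of 29 measured rose, 6 fell and 21 did not pass the test. SDF2L1 fell from 83.3 ± 5.08 to 45.8 ± 5.26 TPM and XBP1 from 68.3 ± 1.64 to 41.9 ± 3.2 TPM. In the unfolded protein response list, the median log2 change was -0.04 and camera gave adjusted p = 0.519, or adjusted p = 0.917 with an estimated correlation. In the unfolded protein response list 2 rose and 6 fell when adjusted over the list alone. Of the heat shock genes, 2 of 22 measured rose, 5 fell and 15 did not pass the test. HSPB1 fell from 884 ± 61.8 to 556 ± 27 TPM and DNAJB6 rose from 95.9 ± 10.6 to 194 ± 24.6 TPM. In the heat shock response list, the median log2 change was -0.10 and camera gave adjusted p = 0.753, or adjusted p = 0.917 with an estimated correlation. In the heat shock response list 2 rose and 5 fell when adjusted over the list alone. Of the NF-kB and inflammatory genes, 5 of 28 measured rose, 3 fell and 20 did not pass the test. The mean log2 change of 0.13 and the direction of the test were upward and the median was not. In the NF-kB list, the median log2 change was -0.05 and camera gave adjusted p = 0.368, or adjusted p = 0.917 with an estimated correlation. PLAU, the urokinase gene, rose from 59.1 ± 3.14 to 109 ± 8.37 TPM. In the NF-kB list 5 rose and 3 fell when adjusted over the list alone. Of the Wnt target and intestinal stem cell genes, 3 of 20 measured rose, 4 fell and 13 did not pass the test. CCND1, cyclin D1, rose from 185 ± 33.7 to 514 ± 94 TPM and SOX9 from 35 ± 7.01 to 82.3 ± 10.9 TPM. In the Wnt list, the median log2 change was -0.17 and camera gave adjusted p = 0.929, or adjusted p = 0.978 with an estimated correlation. In the Wnt list 3 rose and 4 fell when adjusted over the list alone. The direction of the Wnt list turned upward with a mean TPM of at least 5, with a replicate block, with the GC trend removed and without both libraries numbered 1 (adjusted p = 0.688, 0.943, 0.977 and 0.780). It also turned without control siRNA replicate 1, control siRNA replicate 2, RRN3 siRNA replicate 1 or RRN3 siRNA replicate 3 (adjusted p = 0.879, 0.921, 0.973 and 0.967). Of the intestinal differentiation markers, 2 of 7 measured rose, 3 fell and 2 did not pass the test. CEACAM1 rose from 0.632 ± 0.0514 to 3.63 ± 0.712 TPM and DPP4 fell from 4.35 ± 0.85 to 1.32 ± 0.438 TPM. In the differentiation marker list, the median log2 change was -0.30 and camera gave adjusted p = 0.548, or adjusted p = 0.917 with an estimated correlation. In the differentiation marker list 2 rose and 4 fell when adjusted over the list alone. Of the proteasome subunits, 3 of 36 measured rose, 2 fell and 31 did not pass the test. PSMB3 fell from 453 ± 25.3 to 355 ± 24.5 TPM and PSMC4 rose from 107 ± 5.62 to 132 ± 5.83 TPM, and both calls ended with median-of-ratios scaling (adjusted p = 0.205 and 0.0577) and without RRN3 siRNA replicate 2 (adjusted p = 0.0595 and 0.0772). The PSMB3 call also ended with the GC trend removed (adjusted p = 0.0711), and the PSMC4 call without a variance trend (adjusted p = 0.0609) and without control siRNA replicate 1, control siRNA replicate 3 or RRN3 siRNA replicate 3 (adjusted p = 0.0568, 0.0597 and 0.0791). In the proteasome list, the median log2 change was 0.04 and camera gave adjusted p = 0.446, or adjusted p = 0.889 with an estimated correlation. In the proteasome list 0 rose and 0 fell when adjusted over the list alone, and 10 had an unadjusted p under 0.05.

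Markers of other cell types were mostly near 0, with 14 of 15 immune, 10 of 12 fibroblast and 9 of 11 endothelial genes in the table under a mean of 1 TPM. The exceptions were CD68, which fell as given above, ACTA2, which rose, and COL1A1, at 9.3 and 7.17 TPM (adjusted p = 0.102). The endothelial genes ESAM and EGFL7 fell from 6.92 ± 1.24 to 1.91 ± 0.128 TPM and from 86.8 ± 10.7 to 56.7 ± 1.76 TPM. ACTA2 and COL1A1 are also in the epithelial-mesenchymal transition list.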

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

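The GC correction and the fit without both libraries numbered 1 were chosen after seeing the data. RRN3 kept its direction and its side of the threshold under every alternative run, with log2 changes from -3.40 (pseudocount 0.1) to -1.70 (pseudocount 5) and, with each library left out in turn, from -3.07 to -2.60. The p53, G1/S and G2/M lists kept theirs under all alternatives except camera with an estimated correlation, where the adjusted p was 0.703 for each and the number of lists past the threshold went from 16 to 0. Median-of-ratios scaling left 10 lists and leaving out a library in turn 12 to 18. The number of changed genes, 3679, was between 2240 and 4254 with each library left out, with 788 to 1273 rising and 1452 to 3000 falling. The low counts came without RRN3 siRNA replicate 2 (2240 changed, 788 rising, 1452 falling), and without control siRNA replicate 3 the number rising was 893. Fewer samples lower the power, but 4254 genes changed without RRN3 siRNA replicate 1 and 4771 without both libraries numbered 1. The number of samples alone therefore does not account for the low counts. RRN3 siRNA replicates 1 and 3, left without replicate 2, lay farthest apart on the second principal component (31.6 and -23.0). The cause was not tested further. Quantile normalization gave 2205 rising genes and removal of the GC trend 2758, and the cause was not tested. A minimum log2 change of 1 left 809 genes, 272 rising and 537 falling, by construction. Of the 3679 calls, 3464 were also made with the GC trend removed, 3448 with quantile normalization, 3236 after median-of-ratios scaling and 2961 without a filter, with 1, 2, 0 and 0 changes of sign. Without both libraries numbered 1, 3497 of the 3663 calls still tested were made. With single libraries left out, the fewest were 2224 of 3670 without RRN3 siRNA replicate 2, 2600 of 3662 without control siRNA replicate 2 and 2746 of 3660 without control siRNA replicate 3, and the most were 3397 of 3671 without RRN3 siRNA replicate 1. With a replicate block 5546 genes changed, 2295 rising and 3251 falling, and 16 lists passed. All 3679 calls were also made with the block, with 0 changes of sign. The deviations of same-numbered libraries correlated across genes at 0.42, 0.095 and 0.16, and only the libraries numbered 1 each correlated best with their own number, so the labels' numbers were not taken to pair the samples. Deviations within a group are not independent, so these values can neither show a pairing nor set it aside. The RRN3P3 difference of 0.36 moved to 0.71 with a pseudocount of 0.1 and 0.12 with one of 5, by construction. Directions reversed for 4 lists that passed in neither setting, with adjusted p-values as follows. The Wnt list turned upward with a mean TPM of at least 5 (0.688), with the replicate block (0.943), with the GC trend removed (0.977), without both libraries numbered 1 (0.780) and with single libraries left out (0.879 to 0.973). The mitochondrial ribosomal protein list turned upward after median-of-ratios scaling (0.592), rescaling (0.905), GC correction (0.888), without both libraries numbered 1 (0.650) and without control siRNA replicate 3 (0.820) or RRN3 siRNA replicate 1 (0.538). It stayed downward with each other library left out, with the lowest value without RRN3 siRNA replicate 3 (0.340). The cytosolic ribosomal protein list turned upward without RRN3 siRNA replicate 1 (0.802, the highest of a range from 0.00498 with single libraries left out) and without both libraries numbered 1 (0.940), and the polymerase I list without both (0.967). MT-CYB turned to -0.050 with quantile normalization (adjusted p = 0.442), which sets values by rank and can remove changes of such abundant transcripts by construction. The causes of these reversals were not tested. Among the named genes, 71 gene and setting pairs lost the call without turning, among them MT-ND6 with quantile normalization at a log2 change of 0, 1, that of MT-CYB above, turned and also lost it, 4 gained a call and 1986 were unaffected. Sequencing depth is unknown, so what it limits could not be stated.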

Other observations

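The tests of GC content and scaling for the p53 and cell cycle genes and both tests of the histone genes were chosen only after the result was seen. Beyond the lists, mitochondrial ribosomal RNA rose with RRN3 siRNA, MT-RNR1 from 1468 ± 82.5 to 2159 ± 54.9 TPM and MT-RNR2 from 5789.6 ± 63.3 to 8959.6 ± 123 TPM (limma adjusted p = 0.00101 and 0.000592, n = 3 per group, named after their values were seen). Both calls were not checked under the alternatives, among which median-of-ratios scaling, quantile normalization and GC correction ended that of the mitochondrial genome list. Capture and the removal of ribosomal RNA may also bear on both values. The cytosolic 5.8S ribosomal RNA, also chosen after its values were seen, was listed under 2 symbols. The second was above 0 only in control siRNA replicate 3, where the first was at 0, and in RRN3 siRNA replicate 2, where both were above 0. Their sum was 207 ± 22.7 TPM in control siRNA and 242 ± 25.1 TPM in RRN3 siRNA libraries (SD, n = 3, exact permutation p = 0.2). Mature ribosomal RNA was depleted before sequencing per the labels, so these sums are no measure of ribosomal RNA synthesis. The 7SK RNA, likewise chosen and listed under 2 symbols, summed to 9.64 ± 1.27 and 24.3 ± 4.10 TPM (exact permutation p = 0.1, the smallest possible). Of further RNAs, all named after their values were seen, RPPH1, the RNA of RNase P, rose from 5.68 ± 1.02 to 12 ± 1.24 TPM and the signal recognition particle RNA RN7SL1 from 94.5 ± 21.4 to 147 ± 12.9 TPM, while RMRP was at 8.09 and 5.89 TPM (adjusted p = 0.272).

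A scan of 215 groups of genes that share the start of their symbol, with 430 tests for an excess of rises or falls, gave 1 group past the threshold, the keratins, of which 9 of 14 rose and 3 fell (adjusted p = 0.00142). The keratin genes given here were named after their values were seen. KRT19 rose from 1573 ± 131 to 3162 ± 142 TPM, and KRT13 and KRT15 fell from 2.98 ± 0.803 to 0.811 ± 0.358 TPM and from 44.7 ± 1.62 to 28.7 ± 1.4 TPM. The 9 include the pseudogenes KRT8P3, KRT8P36 and KRT8P45 and the antisense gene KRT10-AS1, which share or overlap sequence with keratin genes and may not be separate signals; the scan was not repeated without them.

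The real grouping gave 3679 changed genes, and the highest of the other 9 splits of the 6 libraries into 3 and 3 gave 1. With 10 splits, of which 1 reached the real number, a share under 0.05 cannot be had. Each of the other 9 splits also holds libraries of both groups on each side. A difference between the groups then widens the spread within each side and keeps these counts low, so no conclusion is drawn from them.

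The rise of p53 target genes and the fall of G1/S and G2/M genes were weighed against GC content bias and against the scaling of TPM by abundant transcripts. With the GC trend of each library removed, the median log2 change of the p53 list was 0.88 (0.76 before), and that of both cell cycle lists together -1.47 (-1.53 before). With TPM rescaled without mitochondrial and ribosomal protein genes the medians were 0.81 and -1.56. The shares of these transcripts moved in opposite directions with RRN3 siRNA, mitochondrial from 24.9% to 28.3% and ribosomal protein from 19.2% to 17%. Rescaling could therefore shift values only slightly, and its outcome adds little beyond those shares. Since its outcome was fixed by those shares, no conclusion on scaling is drawn from it. The median log2 change was 0.01 in the tenth of genes with the lowest GC content and -0.18 in that with the highest. Removing so small a trend could change the list medians only slightly. A trend of this size argues against GC content bias as the whole cause. A response of the cells to RRN3 siRNA remains a hypothesis, and an effect of this siRNA on other transcripts stays open, since the design holds 1 siRNA group against RRN3.

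The deviations of both libraries numbered 1 from their group means correlated across genes at 0.42. After removal of the GC trend the correlation was 0.24, a share of 0.572 of the deposited value (95% bootstrap interval over chromosomes 0.473 to 0.649), so GC content can be neither set aside nor named as the main part. Removal of the length trend left 0.42, which argues against transcript length. A shared day or batch may be the source and cannot be tested, since the labels used here give none, and no biological explanation was tested.

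The rise of replication-dependent histone genes was weighed against reads moving between copies and against a larger share of RNA without a poly(A) tail. TPM summed over the 49 listed histone genes was 65.6 ± 5.97 in control siRNA and 210 ± 4.69 in RRN3 siRNA libraries (SD, n = 3), a ratio of 3.20 with no overlap, which argues against reads moving between them. Other RNAs without a poly(A) tail, with 7SK summed over its 2 symbols, had median log2 changes of 0.53 (95% bootstrap interval 0.17 to 0.75, 53 genes) in the classes that the prediction named and 0.45 (0.17 to 0.74, 59 genes) in a wider set, and 0.58 in both when limited to RNAs above 0 in every library, all above 0.43, the bound of 50% of the histone median of 0.85. Before 7SK was summed the values were 0.45 and, in the wider set, which was run first, 0.39; the prediction and both later changes came after values had been seen, and every interval includes the bound. The prediction of a larger share of RNA without a poly(A) tail was thus met in every version except the wider set run first. Only 7SK was summed, and copies of other RNAs were left as listed. The versions were chosen after values had been seen. The test therefore does not decide whether such a share is a source of the rise. All of these medians were under the histone median of 0.85, and the bound asks for 50% of it only. The values therefore do not show that such a share carries the whole rise. A change of histone transcripts with RRN3 siRNA also stays open and was not tested separately.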
